A study of Mus musculus with 90 samples.

How the data were processed

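Total RNA depleted of ribosomal RNA was sequenced from J1 mouse embryonic stem cells and from cells differentiated from them. The lines carry different forms of CBX7, a subunit of Polycomb repressive complex 1 (PRC1) that binds methylated histone H3. WT cells have the normal protein. In CBX7-CaPS the compaction and phase separation domain of the paralog CBX2 was placed in CBX7, in CBX7-mCaPS a mutated form of that domain was used, and the KO line was made to lack CBX7. A further line is named CBX7-CaPS-R in the labels. Each line was differentiated into embryoid bodies in hanging drops (EB series, days 0, 6 and 10) or into neural progenitor cells by aggregation for 4 days and then 5 uM retinoic acid (NPC series, days 0, 6 and 8). Stem cells had been grown on mouse feeder cells that were removed before collection. Each of the 30 groups of line, series and day had 3 libraries, 90 in all.

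The deposited tables hold raw read counts per gene. Per the labels, the authors used cutadapt 1.14, STAR 2.7.0, featureCounts 1.6.3, edgeR and HOMER 4.10.4 with the mouse genome build mm10; which program made which table is not stated. One table per series held the WT, CaPS, mCaPS and KO libraries, and a separate table per series held the CaPS-R libraries. The CaPS-R tables hold part of the genes, so lines were set side by side over the 20824 genes shared in the EB series and the 20930 shared in the NPC series. A partial last line of a CaPS-R table (1 gene) and gene names turned into dates (23 in the EB table, 22 in each CaPS-R table) were left out. Columns of a further line that could not be matched to 9 libraries were not used here. No pair of libraries within a group held identical counts, and pairs from different groups were not checked.

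Counts were fitted in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were left out with filterByExpr, which kept 17791 genes in the EB series and 17818 in the NPC series. Library sizes were scaled by trimmed mean of M values (TMM). Each series was fitted as a single quasi-likelihood model of 36 libraries in 12 groups, with robust dispersion estimates (common dispersion 0.152 in EB and 0.127 in NPC), and each comparison was a two-sided quasi-likelihood F test. Values of p were adjusted by Benjamini and Hochberg over the genes tested, and a gene counts as changed at an adjusted p below 0.05. Fold changes are log2 ratios from the quasi-likelihood fit at the default prior count of edgeR. Large ones near the floor are therefore hardly shrunk. The standard error (SE) given with a fold change was worked back from the test. It is the size of the log2 ratio without a prior count over the square root of F. A prior count of 2 was used only for log2 CPM values made by the cpm function. Levels are CPM after TMM scaling, as the cpm function of edgeR gives them, with the mean and SD of 3 libraries. The p values measure spread between libraries of a group, and the labels do not say whether these come from separate cultures, so that spread may be technical.

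Every line was compared with WT on each day, CaPS was also compared with mCaPS on each day, and the last day of WT was compared with day 0. The WT libraries serve as controls for every line, so comparisons against WT are not independent. The change of CaPS and of CaPS-R from day 0 to the last day relative to that of WT was tested as an interaction in a fit of 45 libraries (15373 genes in EB, 15334 in NPC). The comparison of mCaPS with KO was added after the data had been examined. Changes against WT of different lines were also set side by side as a covariance across genes, with the value that simulated unchanged groups give through their shared WT controls (20 simulations).

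A total of 23 gene lists was written from general knowledge. These cover naive pluripotency, formative pluripotency, primitive streak, mesoderm and cardiac muscle, blood and endothelium, endoderm, neural progenitor, neuron, germline, trophoblast, cleavage stage (genes of the 2-cell embryo), Hox1 to Hox5, Hox6 to Hox13, further developmental transcription factors, retinoic acid response, PRC1, PRC2, cell cycle, CDK inhibitors and p53 targets, hypoxia, immediate early genes, fibroblast and feeder cells, and mitochondrially encoded genes. The last list was not tested because its 13 genes are not in the tables. The other 22 were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 22 lists of a comparison. The estimated adjusted p of a list is its adjusted p with an estimated correlation. Of 704 list tests, 264 passed with the preset correlation and 10 with the estimated one, so list results are weak unless the second value is also small. For each list the number of changed genes is given over all genes and adjusted over the list alone. Lists of imprinted and of Y-linked genes were added after the data had been examined.

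The comparisons, lists, naming rule and most alternatives were chosen before the data were examined. Genes named are Cbx7 and Cbx2 in each comparison, then the 5 highest and 5 lowest fold changes among changed genes with a mean of at least 5 CPM whose libraries do not overlap between the groups, which chance gives for 10% of unchanged genes at 3 against 3. From each list up to 4 members with the smallest adjusted p, or the 2 with the highest CPM where none passed, could be named. Gene models known by a number or clone name were counted and not named. Some genes that meet the rule are not reported here. Genes outside the rule are marked where they appear.

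Alternatives were DESeq2 size factors, no low-count filter, replicate number as a block, a fit of the 2 compared groups alone, a DESeq2 1.42.0 Wald test without independent filtering, leaving out each library in turn, a stricter threshold of 0.01 and a minimum of 10 CPM for the covariance. Added after the data had been examined were fits without the Rn45s gene, without the 2 EB libraries highest in Rn45s, without the 6 WT and CaPS EB libraries numbered 1, with replicate blocks within each day for pairs of lines, and counts without genes that have named pseudogene copies. Replicate numbers were checked for pairing by correlating deviations from group means. Libraries of WT and CaPS with the same number resembled one another in 9 of 9 groups per series (median r 0.77 in EB and 0.64 in NPC across genes), as did those of mCaPS and KO (0.33 and 0.55). For these pairs of lines the blocked value is printed where it changes the result. Other pairs of lines showed no such pairing.

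The method was tested on simulated data with 200 genes changed in 1 group of CaPS. At a log2 change of 1 it recovered 6 of 100 genes in EB and 28 of 100 in NPC, and at a log2 change of 2 it recovered 53 and 54 of 100. It made 3 false calls of 62 in EB and 6 of 88 in NPC. Many changes of 2-fold would therefore be missed.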

Results

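Gene expression was measured by RNA sequencing in mouse stem cells and in their derivatives, for 5 lines, 2 ways of differentiation and 3 days each, with 3 libraries per group (n = 3 for every value below unless stated). Library totals of WT, CaPS, mCaPS and KO were 10.6 to 55.9 M counts in the EB series (median 40.6 M) and 11.8 to 59.3 M in the NPC series (median 39.2 M). The part of the genes held for CaPS-R came to 11.0 to 110.0 M counts in EB and 11.7 to 29.1 M in NPC. Rn45s, the precursor of ribosomal RNA, took 2.7% to 88.7% of the counts of the other 4 lines in EB and 4.2% to 50.3% in NPC, and 25.0% to 65.2% and 27.8% to 80.5% in CaPS-R. The highest shares of the 4 lines were 88.7% in mCaPS day 0 replicate 3 and 63.0% in CaPS day 6 replicate 3 of the EB series. The 6 EB libraries of WT and CaPS numbered 1 stood apart from the rest in their counts. Among counts of 1 to 20, even numbers made up 42.1% to 43.5% in those libraries and 73.5% to 94.1% in the other EB libraries of the 4 lines, and 69.4% to 84.9% in CaPS-R. Gapdh, a glycolytic enzyme gene, was at 5.1 to 13.2 CPM of the counts outside Rn45s there against 79.7 to 623 in the other WT and CaPS libraries of the series.

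The WT time courses show what the normal lines do. In embryoid bodies genes of naive pluripotency fell by day 10, and genes of mesoderm, heart, blood and endoderm rose. Pou5f1, a core pluripotency factor, changed by -2.97 ± 0.40 (log2, SE), from 638 ± 26.3 to 81.5 ± 41.8 CPM (SD), and Dppa4, a pluripotency-associated gene, by -3.60 ± 0.48. Hand1 and Mef2c, transcription factors of the heart, rose by 7.53 ± 1.17 and 5.82 ± 0.70. Kdr, a receptor of endothelial precursors, rose by 5.75 ± 0.84, Lmo2, a blood regulator, by 4.20 ± 0.48, and the endoderm factors Gata6 and Sox17 by 5.66 ± 0.72 and 6.50 ± 0.92. Cbx7 changed by -2.11 ± 0.55 (adjusted p = 0.00433, 25.8 ± 15.8 against 112 ± 30.3 CPM), and Cbx2 by 1.47 ± 0.42 (adjusted p = 0.00936, 83.3 ± 3.93 against 30 ± 2.51 CPM).

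The highest fold changes by the naming rule were those of Hbb-bh1 and Hba-x, embryonic globin genes (9.0 ± 1.64 and 8.30 ± 1.94), Ttr, a transport protein made in yolk sac endoderm (8.31 ± 1.65), Foxb1 (8.16 ± 1.49) and Shh, a morphogen (7.93 ± 1.43). The lowest were Ccl7 and Ccl11, chemokine genes (-9.35 ± 1.28 and -8.76 ± 1.13), Mmp3, a matrix protease gene of fibroblasts (-8.71 ± 0.98), Ereg (-8.70 ± 1.31) and S100a4 (-8.23 ± 1.15). The fibroblast and feeder list had a mean log2(CPM + 1) of 4.53 to 7.27 on day 0, 2.09 to 2.92 on day 6 and 4.28 to 4.81 on day 10. Stem cells had been grown on feeder cells, so feeder RNA left on day 0 was not parted from a change in the stem cells. In all, 2616 genes were higher and 2579 lower on day 10 of EB at an adjusted p below 0.05 by edgeR.

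Of the fixed lists, 16 of 22 passed in WT EB with the preset correlation and 0 with an estimated one. Naive pluripotency genes were lower in 21 of 24 cases (adjusted p = 5.58e-17, and adjusted p = 0.0687 with an estimated correlation). Lower were also 10 of 16 germline genes (adjusted p = 0.000581, estimated adjusted p = 0.216), 9 of 17 immediate early genes (adjusted p = 0.000581, estimated adjusted p = 0.189) and 8 of 20 cell cycle genes (adjusted p = 0.000581, estimated adjusted p = 0.259). Of fibroblast genes 9 of 20 fell (adjusted p = 0.000773, estimated adjusted p = 0.403), and of Hox6 to Hox13 8 of 24 fell (adjusted p = 0.00469, estimated adjusted p = 0.506). On day 0 the Hox6 to Hox13 mean was 0.32, 1.01 and 1.45 in WT replicates 1, 2 and 3. The fibroblast mean rose in the same order, at 4.53, 6.36 and 7.27, so feeder RNA was not parted from either fall. Of the cleavage-stage list 5 of 12 genes fell (adjusted p = 0.00599, estimated adjusted p = 0.403), and of PRC2 genes 4 of 12 fell (adjusted p = 0.0101, estimated adjusted p = 0.0687). Higher were 21 of 24 mesoderm genes (adjusted p = 2.16e-13, estimated adjusted p = 0.0947), 17 of 21 blood genes (adjusted p = 5.05e-08, estimated adjusted p = 0.0687) and 15 of 24 endoderm genes (adjusted p = 2.19e-07, estimated adjusted p = 0.205). Of further developmental factors 22 of 51 rose (adjusted p = 0.000581, estimated adjusted p = 0.403), and of neural progenitor genes 6 of 22 rose (adjusted p = 0.00143, estimated adjusted p = 0.403). Of trophoblast genes 8 of 12 rose (adjusted p = 0.00143, estimated adjusted p = 0.0947), of retinoic acid response genes 9 of 17 (adjusted p = 0.00333, estimated adjusted p = 0.259) and of Hox1 to Hox5 8 of 15 (adjusted p = 0.00469, estimated adjusted p = 0.403). Adjusted over the list alone, the counts for naive, mesoderm and blood genes did not move. In the same way 17 endoderm, 26 further developmental, 11 immediate early, 12 fibroblast and 10 Hox6 to Hox13 genes passed. Lists that did not pass were CDK inhibitors and p53 targets (adjusted p = 0.13, 2 genes higher and 3 lower), primitive streak (0.243, 8 and 3) and hypoxia (0.243, 2 and 3). Nor did neuron (0.356, 2 and 4), PRC1 (0.356, 6 and 5) and formative pluripotency (0.422, 2 and 2).

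In the NPC series WT cells lost naive pluripotency genes and gained Hox1 to Hox5, retinoic acid response and neural genes by day 8. Tdgf1, a Nodal co-receptor of stem cells, fell by 7.99 ± 0.64, from 251 ± 95.6 to 0.994 ± 0.447 CPM, and Esrrb, a naive pluripotency factor, by 6.38 ± 0.53. Hoxc4, which patterns the body axis, rose by 6.18 ± 0.37, Rarb, a retinoic acid receptor, by 6.70 ± 0.38, and Meis1, a Hox cofactor, by 5.00 ± 0.24. Sox11, a factor of neural precursors, rose by 4.53 ± 0.40 to 1610 ± 263 CPM, and Onecut2, a factor of neuronal differentiation, by 5.39 ± 0.52. Cbx7 fell by 3.16 ± 0.34 (adjusted p = 2.95e-08, 19 ± 1.67 against 170 ± 18.1 CPM) and Cbx2 rose by 1.38 ± 0.23 (adjusted p = 1.75e-05, 84.9 ± 4.14 against 32.6 ± 1.67 CPM). The highest fold changes were those of the neuronal factor Neurod4 (9.15 ± 1.59), Wnt1 (8.50 ± 1.44), Pax7 (8.03 ± 1.30), St18 (8.02 ± 1.40) and Nhlh2 (8.01 ± 1.23). Among the lowest were Krt42 (-10.41 ± 1.19), Il1rl1 (-9.19 ± 1.41), Serpina3h (-9.14 ± 1.35) and Mmp3 (-8.98 ± 1.12). The fibroblast and feeder mean was 4.56 to 6.95 on day 0 and 2.53 to 3.36 on day 8, so feeder RNA was not parted here either. By edgeR 4903 genes were higher and 4439 lower.

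Of the lists, 13 of 22 passed in WT NPC with the preset correlation. Those that also passed with an estimated correlation were Hox1 to Hox5, retinoic acid response and naive pluripotency. In Hox1 to Hox5 15 of 15 genes rose (adjusted p = 1.93e-25, estimated adjusted p = 0.000972), in retinoic acid response 15 of 17 rose and 1 fell (adjusted p = 2.51e-14, estimated adjusted p = 0.000972), and in naive pluripotency 23 of 24 fell (adjusted p = 6.23e-23, estimated adjusted p = 0.0151). Neural progenitor genes rose in 21 of 22 cases (adjusted p = 5.56e-08, and adjusted p = 0.268 with an estimated correlation). So did 16 of 21 neuron genes (adjusted p = 1.32e-05, estimated adjusted p = 0.268) and 24 of 51 further developmental factors (adjusted p = 0.0105, estimated adjusted p = 0.268). Lower were 17 of 20 fibroblast genes (adjusted p = 4.96e-05, estimated adjusted p = 0.322), 12 of 17 immediate early genes (adjusted p = 0.000202, estimated adjusted p = 0.138) and 11 of 20 cell cycle genes (adjusted p = 0.00199, estimated adjusted p = 0.561). Of primitive streak genes 8 of 15 fell (adjusted p = 0.0105, estimated adjusted p = 0.268), and of germline genes 8 of 16 (adjusted p = 0.0273, estimated adjusted p = 0.502). Of PRC2 genes 6 of 12 fell (adjusted p = 0.0307, estimated adjusted p = 0.138), and of formative genes 7 of 12 (adjusted p = 0.0337, estimated adjusted p = 0.268). Adjusted over the list alone, the counts were 22 neural progenitor, 19 fibroblast and 13 immediate early genes. Lists that did not pass were endoderm (adjusted p = 0.0828, 11 higher and 4 lower), CDK inhibitors and p53 targets (0.152, 2 and 9), PRC1 (0.528, 12 and 6) and the cleavage-stage list (0.646, 1 and 2). Mesoderm (0.646, 8 and 2), Hox6 to Hox13 (0.646, 9 and 6), blood (0.646, 4 and 6), trophoblast (0.785, 3 and 3) and hypoxia (0.835, 4 and 2) did not pass either.

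The comparison of CaPS with WT asks what the CBX2 domain does when it sits in CBX7. Reads from the added domain may count toward Cbx2 in CaPS and mCaPS, which was not tested, so Cbx2 values of these lines are uncertain. In embryoid bodies almost no gene passed the test. Cbx7 itself was at -0.48 ± 0.53, 0.44 ± 0.53 and 1.27 ± 0.53 on days 0, 6 and 10 (adjusted p = 0.915 on day 10, 62.1 ± 28.4 against 25.8 ± 15.8 CPM), and Cbx2 at 0.26, 0.59 and 0.14. The gene that passed was Peg13, an imprinted noncoding RNA gene (15:72805602 to 72810324, minus strand), lower on day 10 by -3.54 ± 0.60 (adjusted p = 0.038, 0.637 ± 0.339 against 7.54 ± 2.52 CPM). With libraries paired by number within each day, in a fit of the 2 lines only, its adjusted p was 0.115. It lies outside the naming rule and was chosen after its values were seen. Neuron genes were higher as a list on day 10 (adjusted p = 4.39e-15, and adjusted p = 0.0839 with an estimated correlation), with 0 of 22 changed over all genes and 13 adjusted over the list alone. Tubb3, a neuronal tubulin (8:123411553 to 123422015, plus strand), was at 3.01 ± 0.63 (adjusted p = 0.0949, 139 ± 201 against 17.2 ± 5.2 CPM). CaPS replicate 3 stood apart there, with a mean log2(CPM + 1) of the neuron list of 4.68 against 1.85 to 2.47 in the other WT and CaPS libraries. The same replicate stood apart on day 6 in mesoderm and cardiac muscle genes (4.08 against 0.73 to 1.35). That list was higher on day 6 (adjusted p = 4.66e-18, and adjusted p = 0.235 with an estimated correlation; 0 genes over all and 14 adjusted over the list alone). Myh6, a cardiac myosin, was at 4.43 ± 1.04 (adjusted p = 0.342).

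By edgeR 0, 0 and 1 genes differed between CaPS and WT on EB days 0, 6 and 10, with 255, 971 and 763 at an unadjusted p below 0.05, and DESeq2 gave 0, 75 and 74. With libraries paired by number within each day the day 10 count was 0. Without CaPS replicate 1, 2 or 3 the count was 24, 16 or 1 on day 6 and 83, 77 or 0 on day 10, and without WT replicate 2 or 3 it was 0 on day 10.

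**Figure D1:**
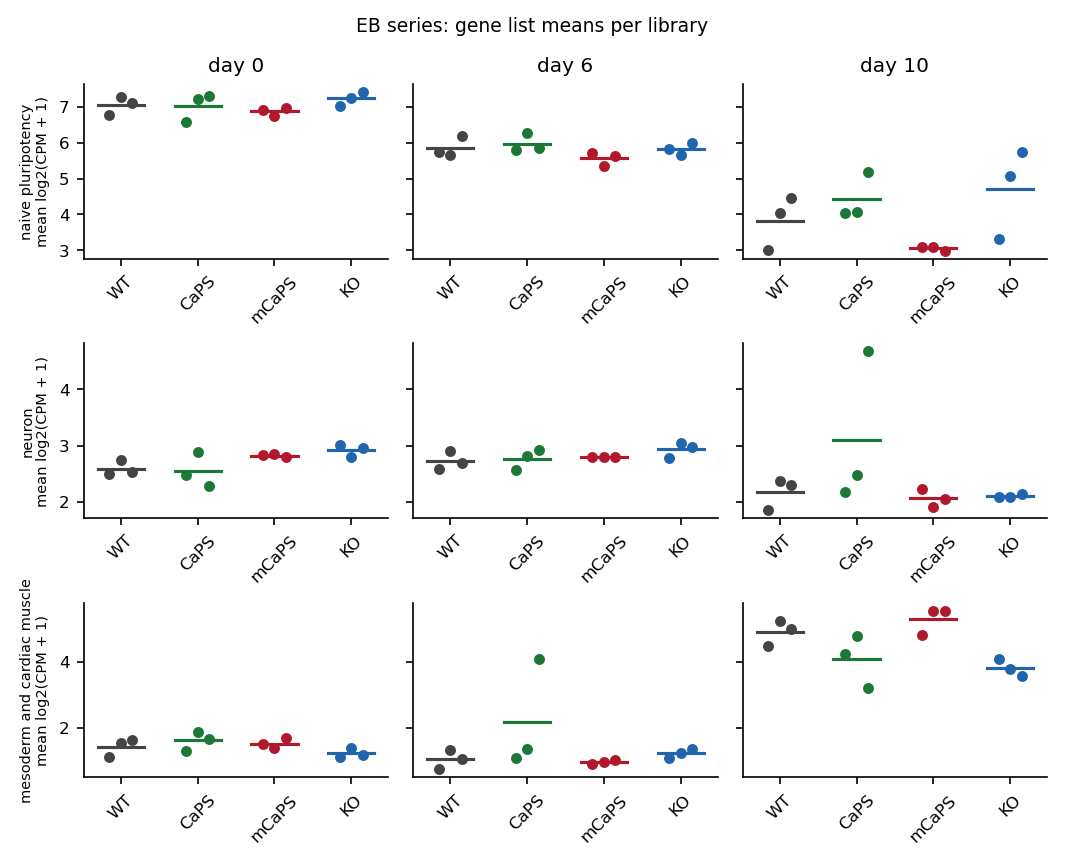
Mean log2(CPM + 1) of naive pluripotency, neuron, and mesoderm and cardiac muscle genes (y axes) in the WT, CaPS, mCaPS and KO libraries of the EB series on days 0, 6 and 10; points are libraries and lines are means of 3. CaPS replicate 3 lies apart at 4.68 for neuron genes on day 10 and at 4.08 for mesoderm genes on day 6.

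By NPC day 8 CaPS cells had lower levels of the imprinted genes Peg13 and Nnat and a mixed picture of neural and mesodermal genes. Peg13 was at -4.44 ± 0.60 (adjusted p = 0.000668, 1.35 ± 0.662 against 29.3 ± 14.6 CPM). Nnat, an imprinted gene active in brain (2:157560078 to 157562525, plus strand), was at -2.27 ± 0.38 (adjusted p = 0.0145, 23.6 ± 6.16 against 114 ± 41.6 CPM). Without WT replicate 1 or CaPS replicate 2 or 3 the adjusted p of Nnat was 0.221, 0.282 or 0.301. Cbx7 was at -0.15, 0.83 ± 0.32 and 1.55 ± 0.33 on days 0, 6 and 8 (adjusted p = 0.0798 on day 8, 55.8 ± 13.4 against 19 ± 1.67 CPM). Cbx2 was at 0.91 ± 0.23, 0.22 and 0.28 (adjusted p = 0.529 on day 0). Mesoderm genes were higher as a list on day 6 (adjusted p = 6.96e-15, and adjusted p = 0.0868 with an estimated correlation; 0 over all genes and 15 adjusted over the list alone) and on day 8 (adjusted p = 6.05e-08, estimated adjusted p = 0.297). Neuron genes were lower as a list on day 6 (adjusted p = 6.53e-10, estimated adjusted p = 0.237) and on day 8 (adjusted p = 6.05e-08, estimated adjusted p = 0.297), with 1 of 21 above 0 on day 8 and 0 changed over all genes. Paired by number within day 8, 11 mesoderm genes were higher and 10 neuron genes lower adjusted over the list alone. The CaPS libraries parted here. On day 8 the neuron mean was 6.11 in replicate 1, 3.53 in replicate 2 and 4.79 in replicate 3, against 5.74 to 6.17 in WT. The mesoderm mean was 1.29, 3.35 and 3.07 against 1.13 to 1.91. On day 0 formative pluripotency genes were higher as a list (adjusted p = 4.83e-06, and adjusted p = 0.0357 with an estimated correlation), with fold changes above 0 in 11 of 12, 0 changed over all genes and 1 adjusted over the list alone. Among them was Dnmt3b, a DNA methyltransferase, at 0.72 ± 0.21 (adjusted p = 0.694, 866 ± 186 against 526 ± 119 CPM).

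By edgeR 0, 0 and 2 genes differed between CaPS and WT on NPC days 0, 6 and 8, with 639, 1175 and 1567 at an unadjusted p below 0.05, and DESeq2 gave 8, 119 and 226. Paired by number within each day the counts were 55, 28 and 251. Without CaPS replicate 1 they were 7, 201 and 801, and without WT replicate 1 or CaPS replicate 2 or 3 the day 8 count was 1.

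**Figure D2:**
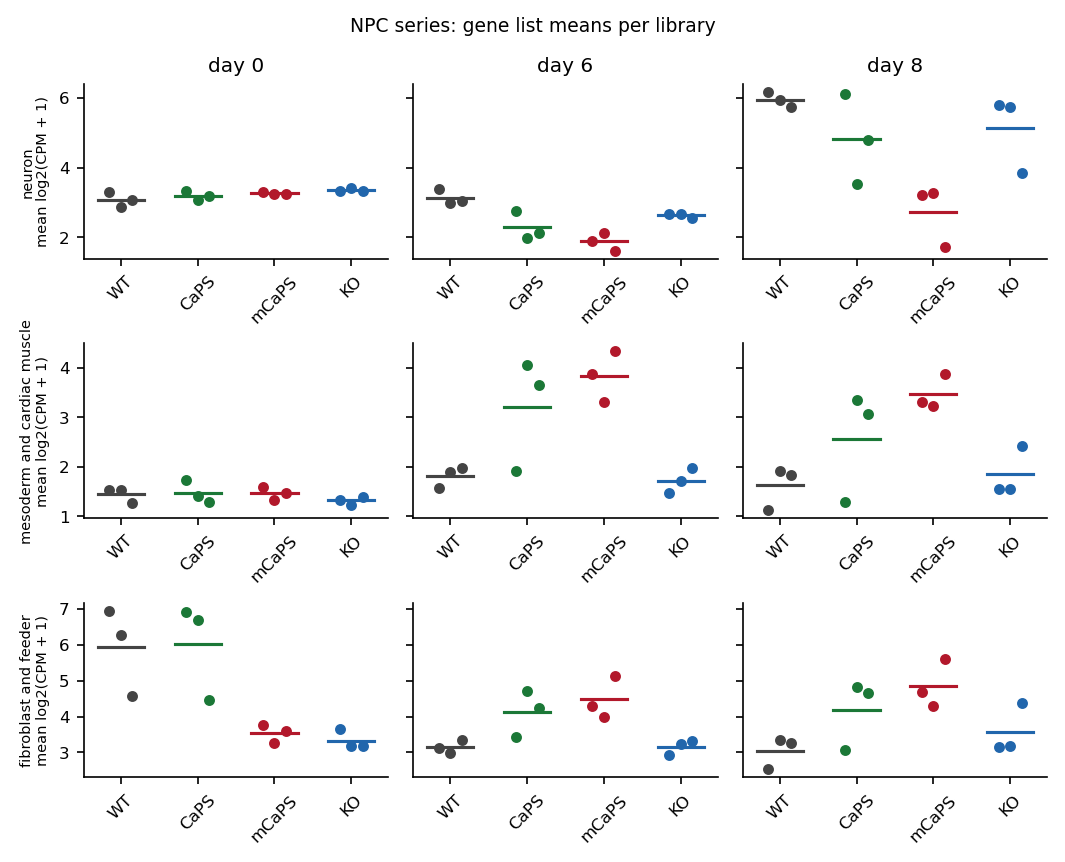
Mean log2(CPM + 1) of neuron, mesoderm and cardiac muscle, and fibroblast and feeder genes (y axes) in the WT, CaPS, mCaPS and KO libraries of the NPC series on days 0, 6 and 8; points are libraries and lines are means of 3. On day 8 neuron genes lie at 5.74 to 6.17 in WT and at 1.73 to 3.27 in mCaPS, with CaPS between 3.53 and 6.11.

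CaPS and mCaPS differ in the added domain, so their comparison asks what depends on its intact form. In EB the 2 lines also lie in different library sets, so form and set run together there. On EB day 10 naive pluripotency genes were higher in CaPS, and so were neuron and neural progenitor genes, largely through CaPS replicate 3. Tdgf1 was higher by 2.49 ± 0.44 (112 ± 45.8 against 19.9 ± 2.5 CPM), Gdf3, a growth factor of stem cells, by 3.80 ± 0.63 and Lefty2, a Nodal inhibitor, by 3.01 ± 0.49. Tubb3 was higher by 4.00 ± 0.66 and Elavl3, an RNA-binding protein of neurons, by 4.13 ± 0.83. Bmp4, a mesoderm-inducing signal, was lower (-1.44 ± 0.37), and Cbx7 was higher by 2.60 ± 0.56 (adjusted p = 0.00636, 62.1 ± 28.4 against 10.2 ± 1.1 CPM) with Cbx2 at 0.03. Of the naive list 14 of 24 genes were higher, 16 adjusted over the list alone (adjusted p = 1.28e-15, and adjusted p = 0.141 with an estimated correlation). Of the neuron list 10 of 22 were higher, or 17 over the list alone (adjusted p = 2.32e-07, estimated adjusted p = 0.435), and of the neural progenitor list 7 of 22, or 9 over the list alone (adjusted p = 0.00189, estimated adjusted p = 0.446). CaPS replicate 3 had a neuron mean of 4.68 and a neural progenitor mean of 5.01. The other CaPS libraries had 2.17 and 2.47 for neuron and 2.05 and 2.49 for neural progenitor, against 1.91 to 2.23 and 2.11 to 2.5 in mCaPS. Without replicate 3 Tubb3 was at 1.42 (adjusted p = 0.0441), Elavl3 at 1.61 (adjusted p = 0.333), Fabp7 at 1.57 (adjusted p = 0.568) and Kirrel2 at 3.33 (adjusted p = 0.152).

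The highest named genes on EB day 10 were Kirrel2 (7.34 ± 1.35), Fabp7, a fatty acid carrier of radial glia (6.27 ± 1.26), Rpl23a (5.67 ± 0.92) and Rpl5 (5.60 ± 0.41). The lowest were Btg3 (-5.42 ± 0.72), Mir682 (-4.91 ± 0.58), Peg13 (-4.33 ± 0.62) and Hmga2-ps1 (-4.31 ± 0.61). Rpl5, Rpl23a, Btg3 and Hmga2-ps1 are or have pseudogene copies, so their reads may be shared and their values are uncertain. On EB day 6 cardiac muscle genes were higher in CaPS, such as Myh7 (5.85 ± 1.17, 30.8 ± 51 against 0.518 CPM) and Actc1 (5.19). This held for 9 of 24 list genes, or 17 adjusted over the list alone (adjusted p = 1.8e-11, and adjusted p = 0.557 with an estimated correlation). CaPS replicate 3, with 63.0% Rn45s, carried this, with a list mean of 4.08 against 1.09 and 1.35 in the other CaPS libraries and 0.89 to 1.02 in mCaPS. Without it Myh7 was at 1.37 (adjusted p = 0.845) and Actc1 at 1.20 (adjusted p = 0.893). Without mCaPS replicate 1, 2 or 3 neither passed, with Myh7 at 5.76 to 5.96 (adjusted p = 0.0533 to 0.0704). On EB day 0 Cbx2 was lower by -2.11 ± 0.43 (adjusted p = 0.00648), with an uneven mCaPS group (155 ± 156 against 35.9 ± 3.14 CPM in CaPS) whose replicate 3 has the highest Rn45s share. Without mCaPS replicate 3 it was at -0.95 (adjusted p = 0.294), and without CaPS replicate 3 at -2.04 (adjusted p = 0.0595). Cbx7 was at -1.29 then. On day 6 Cbx7 was at 0.96 and Cbx2 at 0.46.

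By edgeR 110, 165 and 481 genes were higher and 31, 34 and 84 lower in CaPS than in mCaPS on EB days 0, 6 and 10. Without CaPS replicate 1, 2 or 3 the day 6 total was 366, 363 or 96, and without mCaPS replicate 1, 2 or 3 it was 89, 86 or 92. The day 10 total was 173 without CaPS replicate 3, and 267, 198 or 225 without mCaPS replicate 1, 2 or 3.

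During NPC differentiation neuron genes were higher in CaPS than in mCaPS on day 8, in calls that rest on single libraries. Their mean was 6.11, 3.53 and 4.79 in CaPS and 3.23, 3.27 and 1.73 in mCaPS. Without CaPS replicate 1, and without mCaPS replicate 3, none of Map2, Crmp1, Stmn2 and Prdm13 passed (adjusted p = 0.5 to 0.581 and 0.15 to 0.34), and 2 genes and 1 gene were left in all. Without mCaPS replicate 2 they did not pass either (adjusted p = 0.0538 to 0.105), and the fit of the 2 groups alone gave 0 genes. Map2, a dendrite protein, was higher by 3.36 ± 0.64 (166 ± 194 against 16.1 ± 10.2 CPM), Crmp1, an axon guidance protein, by 3.80 ± 0.74, Stmn2 by 2.82 ± 0.57 and Prdm13, a factor of spinal interneurons, by 5.00 ± 1.32. The highest was Mir9-3hg, host of a neural microRNA (6.66 ± 1.32), with Glra1 (4.83 ± 0.97), Dner (4.54 ± 1.04) and St18 (4.53 ± 1.12). Lower were H19, an imprinted noncoding RNA (7:142575530 to 142578146, minus strand; -2.99 ± 0.67, 37.1 ± 22.4 against 294 ± 133 CPM), Net1 (-1.58 ± 0.34) and Zmat3, a p53 target (-0.86 ± 0.19). Of the neuron list 11 of 21 genes were higher, 19 adjusted over the list alone (adjusted p = 3.35e-16, and adjusted p = 0.167 with an estimated correlation). Of the neural progenitor list 2 of 22 were higher, or 13 over the list alone (adjusted p = 3.39e-09, estimated adjusted p = 0.412). Cbx7 was higher by 2.11 ± 0.33 (adjusted p = 0.00495, 55.8 ± 13.4 against 13 ± 2.14 CPM) and Cbx2 was at 0.41.

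On NPC day 6 2 genes passed. One was Kcnq1ot1, an imprinted antisense RNA (7:143213111 to 143296547, minus strand), at 2.15 ± 0.35 (adjusted p = 0.0223, 152 ± 20.7 against 34.1 ± 2.81 CPM). The other was Cbx7 (15:79915807 to 79932646, minus strand) at 1.89 ± 0.33 (adjusted p = 0.0293, 71.2 ± 25 against 19.2 ± 6.8 CPM). On NPC day 0 fibroblast and feeder genes were higher in CaPS, such as Mgp (7.77), Prrx1 (4.68 ± 0.67) and Dcn (4.59). This held for 15 of 20 genes, or 17 adjusted over the list alone (adjusted p = 1.98e-24, and adjusted p = 0.0207 with an estimated correlation). Their mean was 4.47 to 6.92 in the CaPS libraries and 3.26 to 3.76 in mCaPS. Hox1 to Hox5 moved the same way (6 of 15 higher, adjusted p = 3.76e-14, estimated adjusted p = 0.0207), as did Hox6 to Hox13 (2 higher, adjusted p = 2.89e-10, estimated adjusted p = 0.043). Retinoic acid response genes did so too (2 of 17 higher, adjusted p = 1.89e-05, estimated adjusted p = 0.0482). Levels of the Hox lists were low, with a Hox1 to Hox5 mean of 1.25 to 1.34 in CaPS and 0.37 to 1 in mCaPS. Feeder RNA in the CaPS libraries was not parted from a change of these lists in the stem cells. Cbx7 was at 0.73 (adjusted p = 0.304).

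By edgeR 305, 2 and 208 genes were higher and 70, 0 and 76 lower in CaPS than in mCaPS on NPC days 0, 6 and 8. Without CaPS replicate 1, 2 or 3 the day 0 total was 193, 77 or 821, and without mCaPS replicate 1, 2 or 3 it was 61, 80 or 242. Leaving out any 1 library gave 0 or 1 on day 6, and on day 8 the total was 2 or 805 without CaPS replicate 1 or 2, and 676, 15 or 1 without mCaPS replicate 1, 2 or 3.

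Comparing mCaPS with WT asks what the altered protein changes when the domain is mutated. In the EB series line and library set run together, since WT and CaPS libraries lie apart from those of mCaPS and KO. Some of the changed genes are or have pseudogene copies, as Rpl5 does, whose reads may be shared, so their values are uncertain. Rpl5 (5:107900528 to 107909005, plus strand) was at 8.45 ± 0.65 CPM in mCaPS and 502 ± 167 in WT on day 10 (-5.89 ± 0.42), and at -5.33 ± 0.41 and -5.61 on days 0 and 6. Mir682 was higher on all 3 days (5.20, 4.75 and 5.09). These 2 genes set the EB libraries of WT and CaPS apart rather than those of mCaPS, since WT of the NPC series on day 0 had 9.87 to 18.2 CPM of Rpl5 and 140 to 260 of Mir682. In EB on that day Rpl5 was at 12.3 in mCaPS against 505 in WT and Mir682 at 206 against 5.55. Aside from these, Lhx1, a factor of early mesendoderm, and Fgf5, a marker of primed pluripotency, were higher on day 0 (5.08 ± 1.27 and 3.52 ± 0.79), and Gdf3 (-2.53) and Lefty2 (-1.99) were lower on day 10. Cbx2 was at 2.36 ± 0.44 on day 0 (adjusted p = 0.00186, 155 ± 156 against 30 ± 2.51 CPM) and at 0.13 and 0.12 on days 6 and 10. Without mCaPS replicate 3, the library with the most Rn45s, it was at 1.22 on day 0 (adjusted p = 0.109). Cbx7 was at 0.81, -0.52 and -1.33 (adjusted p = 0.593 and 0.55 on days 0 and 10).

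Lists gave weaker signals. On EB day 0 primitive streak genes were higher (adjusted p = 1.86e-05, and adjusted p = 0.334 with an estimated correlation; 1 gene, or 10 adjusted over the list alone). On day 10 naive genes were lower (adjusted p = 3.68e-10, estimated adjusted p = 0.533; 2 genes, or 10 over the list alone). By edgeR 50, 23 and 28 genes were higher and 113, 73 and 98 lower in mCaPS on days 0, 6 and 10. Without mCaPS replicate 1 or 2 the day 0 total was 287 (159 higher and 128 lower) or 267 (152 and 115), and without WT replicate 2 it was 97. DESeq2 gave 219 higher and 181 lower on day 0, so which direction held more genes depended on the fit. Leaving out all genes that are or have named pseudogene copies left 107, 44 and 69 genes.

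**Figure D3:**
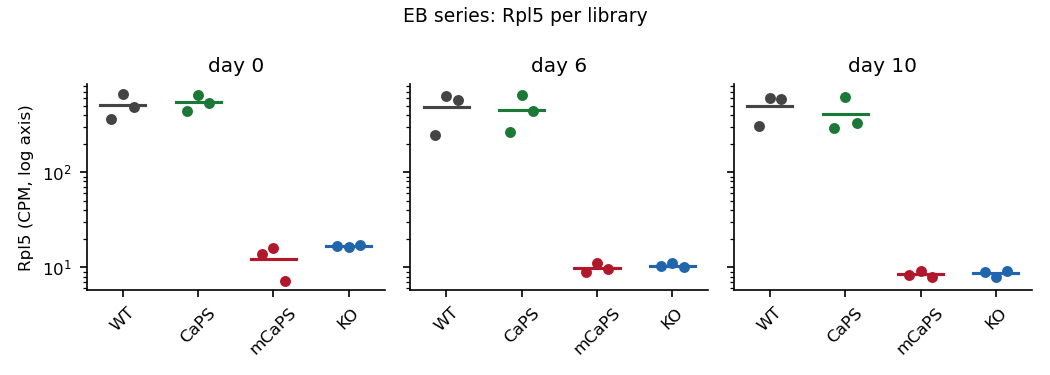
Rpl5 in CPM on a log axis (y) in the WT, CaPS, mCaPS and KO libraries of the EB series on days 0, 6 and 10; points are libraries and lines are means of 3. On day 10 mCaPS averages 8.45 and WT 502 CPM.

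In the NPC series neural genes were lower in mCaPS and mesodermal, blood and fibroblast genes were higher on day 8. Tubb2b, a tubulin of young neurons, was at 79.4 ± 22.7 CPM in mCaPS and 556 ± 112 in WT (-2.81 ± 0.42), Map2 at -4.26 ± 0.66, Sox21, a neural progenitor factor, at -4.17 and Dll1, a Notch ligand, at -3.54. Higher were the heart factors Hand2 (5.62 ± 1.25) and Gata4 (3.79), the cardiac light chain Myl7 (4.51) and Kdr (3.20). So were Twist2, a mesenchymal factor (4.12), Col3a1, a fibrillar collagen (3.71 ± 0.89, 719 ± 520 against 54.9 ± 29 CPM), and Cdkn1a, a p53 target (1.64 ± 0.49). After Hand2 the highest were Apoa1 (5.32), Upk3b (5.29) and Bnc1 (5.05). The lowest were Mir9-3hg (-7.63 ± 1.37), Olig3 (-7.37 ± 1.40), Glra1 (-6.38 ± 1.04) and Prdm13 (-6.34). Cbx7 was at -0.55 (adjusted p = 0.235) and Cbx2 at -0.13.

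As lists on NPC day 8, 19 of 21 neuron genes were lower, as many as adjusted over the list alone (adjusted p = 9.96e-18, and adjusted p = 0.0963 with an estimated correlation). So were 16 of 22 neural progenitor genes, or 19 over the list alone (adjusted p = 8.37e-12, estimated adjusted p = 0.251). Higher were 14 mesoderm genes, or 18 over the list alone (adjusted p = 6.89e-08, estimated adjusted p = 0.251), and 13 blood genes, or 15 (adjusted p = 4.82e-08, estimated adjusted p = 0.332). Fibroblast genes were higher in 12 cases, or 15 (adjusted p = 6.89e-06, estimated adjusted p = 0.332), and endoderm genes in 9 with 1 lower (adjusted p = 0.000461, estimated adjusted p = 0.332). Of CDK inhibitors and p53 targets 6 were higher, or 7 (adjusted p = 0.00161, estimated adjusted p = 0.332). Replicate 3 of mCaPS stood apart, with a mean of 6.07 for this list against 5.31 and 5.37, 6.03 for cell cycle against 6.85 and 6.94, and 1.73 for neuron against 3.23 and 3.27. Without it Cdkn1a was at 1.25 (adjusted p = 0.147), and without WT replicate 1 at 1.5 (adjusted p = 0.0975). On day 6 Hand1 (6.75 ± 1.36) and Tbx20 (5.62 ± 1.00) of the heart were higher and Tubb3 (-4.61 ± 1.00) and Neurog1, a neurogenic factor (-4.75), lower. Mesoderm genes passed in 12 cases, or 16 over the list alone (adjusted p = 7.56e-13, estimated adjusted p = 0.153), and neuron genes in 6, or 13 (adjusted p = 6.15e-10, estimated adjusted p = 0.16). Cbx7 was at -1.06 (adjusted p = 0.076) and Cbx2 at -0.03.

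On NPC day 0 fibroblast and feeder genes were lower in 14 of 20 cases, or 17 adjusted over the list alone (adjusted p = 6.65e-19, and adjusted p = 0.105 with an estimated correlation), with Saa3 (-7.86 ± 1.04), Mgp (-7.73) and Prrx1 (-4.45) as examples. Their mean was 4.56 to 6.95 in the WT libraries and 3.26 to 3.76 in mCaPS. Krt19, an epithelial gene, was higher (3.40 ± 0.87), with Cbx7 at -0.89 (adjusted p = 0.13) and Cbx2 at 0.58 (adjusted p = 0.175). By edgeR 187, 240 and 1674 genes were higher and 351, 155 and 1614 lower in mCaPS on NPC days 0, 6 and 8. Without WT replicate 1 or 2 the day 0 total was 312 or 153, and without mCaPS replicate 1 or 2 it was 91 or 199. The day 6 total was 12, 2 or 108 without WT replicate 1, 2 or 3 and 30, 735 or 0 without mCaPS replicate 1, 2 or 3, and the day 8 total was 1395 without WT replicate 1 and 1205 without mCaPS replicate 3.

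**Figure D4:**
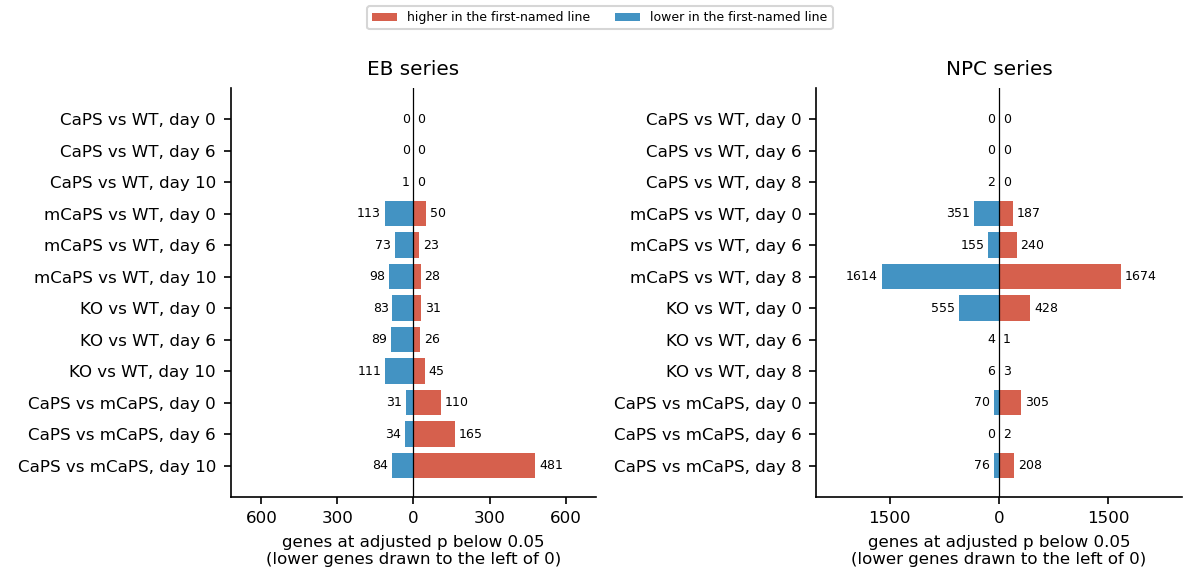
Genes higher (to the right) and lower (to the left) in the first-named line at an adjusted p below 0.05 by edgeR (x axis), for each comparison and day (y axis) of the EB and NPC series. The fit drawn does not pair libraries by number. In it CaPS against WT gives at most 2 genes, and mCaPS against WT on NPC day 8 gives 1674 higher and 1614 lower. Paired by number within each day, CaPS against WT gives 55, 28 and 251 genes on NPC days 0, 6 and 8.

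The KO comparison asks what loss of CBX7 changes. Counts over the whole Cbx7 gene did not pass the test against WT, at -0.20, 0.05 and 1.05 on EB days 0, 6 and 10 (adjusted p = 0.97 and 0.539 on days 0 and 10). They were at -0.47, -0.32 and 0.54 on NPC days 0, 6 and 8 and do not check the deletion. Cbx2 (11:119023021 to 119031275, plus strand) was at 0.46, -0.01 and -0.09 in EB and 0.14, -0.23 and -0.36 in NPC. Grb10, an imprinted growth inhibitor (11:11930499 to 12037420, minus strand), was lower at every time. It was at 21.1 ± 11.2 against 1110 ± 102 CPM on EB day 10 (-5.72 ± 0.37, adjusted p = 1.15e-11). It was at 8.00 ± 2.09 against 1200 ± 27.3 on NPC day 6 (-7.22 ± 0.39) and 19.6 ± 9.74 against 856 ± 69.7 on NPC day 8 (-5.45 ± 0.36). On EB days 0 and 6 and NPC day 0 it was at -2.35, -2.10 and -1.78.

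In KO embryoid bodies Rpl5 was lower on all 3 days (-4.91, -5.54 and -5.86) and Mir682 higher on all 3 (5.11, 4.56 and 4.97), as in mCaPS. Here too the EB libraries of WT stand apart, since KO on day 0 had 16.8 CPM of Rpl5 and 193 of Mir682, close to WT of the NPC series. On day 10 the cardiac genes Myl2 (-4.73), Myl7 (-4.37 ± 0.99) and Myh6 (-4.58 ± 1.04) were lower and Dppa4 (1.92 ± 0.45) and Lefty2 (1.98) higher. Mesoderm genes were lower in 3 cases, or 8 adjusted over the list alone (adjusted p = 1.76e-05, and adjusted p = 0.668 with an estimated correlation). Naive genes were higher in 1, or 10 over the list alone (adjusted p = 2.17e-06, estimated adjusted p = 0.668). KO replicates 2 and 3 carried this, with a naive mean of 5.08 and 5.73 against 3.32 in replicate 1 and 3 to 4.45 in WT. Replicates 2 and 3 of KO also had low sums of Y-linked genes that day, at 9.7 and 6.7 CPM against 72 in replicate 1. Without KO replicate 2 or 3 the adjusted p of Dppa4 was 0.113 or 0.452, and without WT replicate 1, 2 or 3 it was 0.176, 0.0846 or 0.0808. Cleavage-stage genes were higher on day 0 (adjusted p = 1.29e-10, estimated adjusted p = 0.159; 10 over the list alone) and day 6 (adjusted p = 5.17e-11, estimated adjusted p = 0.169; 11 over the list alone), with 0 changed over all genes; many belong to multi-copy families whose reads may be shared, so their values are uncertain. By edgeR 31, 26 and 45 genes were higher and 83, 89 and 111 lower on days 0, 6 and 10. Without KO replicate 1, 2 or 3 the day 10 total was 298, 87 or 85, without WT replicate 2 it was 97, and without KO replicate 3 the day 6 total was 75. Leaving out genes with named pseudogene copies left 64, 57 and 92.

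In the NPC series KO cells had few changed genes after day 0. On day 6 the 5 genes were Grb10, the Y-linked genes Uty (-3.67 ± 0.37), Ddx3y (-3.51 ± 0.30) and Eif2s3y (-3.28 ± 0.34), and the imprinted gene Zrsr1 (1.01 ± 0.18). On day 8 Uty (-3.29), Eif2s3y (-3.01), Ddx3y (-2.97) and Zrsr1 (0.96) were again among the 9 changed genes, now with Ptn, a growth factor (-2.65 ± 0.45), and Impact, an imprinted gene (1.42 ± 0.27). Sums of Y-linked genes were not low in all KO libraries, since KO replicate 1 of EB had 60.4 to 88.9 CPM. In EB, day 0 replicate 3 of CaPS (11.2 CPM) and of mCaPS (14.5 CPM) was low too. Low Y-linked levels thus did not follow the KO line throughout, although the KO libraries of NPC all had 6 to 15.2 CPM. On day 0 fibroblast and feeder genes were lower in 16 of 20 cases, or 17 adjusted over the list alone (adjusted p = 1.59e-17, and adjusted p = 0.154 with an estimated correlation), with Saa3 at -8.25 and Mmp3 at -6.67. Of trophoblast genes 6 were higher (adjusted p = 0.000111, estimated adjusted p = 0.321), such as Gata3 (2.89). Their fibroblast mean was 3.17 to 3.65. On day 8 genes of CDK inhibitors and p53 targets were higher as a list (adjusted p = 0.000258, estimated adjusted p = 0.679; 0 over all genes and 6 over the list alone). KO replicate 3 stood apart there, with a list mean of 6.12 against 4.79 and 5.10 in the other KO libraries and 4.80 to 4.95 in WT, and with a cell cycle mean of 5.83 against 6.62 to 7.05.

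By edgeR 428, 1 and 3 genes were higher and 555, 4 and 6 lower in KO on NPC days 0, 6 and 8. DESeq2 gave 1594, 8 and 130 genes. Without KO replicate 1, 2 or 3 the day 0 total was 225, 318 or 1984 and the day 8 total 122, 35 or 5. Without WT replicate 1 or 2 the day 0 total was 408 or 412, and without WT replicate 1 the day 8 total was 5.

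Genes on chromosome 8 were higher as a group in KO. Relative to all autosomes, their median in KO minus that in mCaPS was 0.44, 0.51 and 0.53 (log2) on EB days 0, 6 and 10 and 0.52, 0.51 and 0.54 on NPC days 0, 6 and 8, over 612 and 635 genes. The other autosomes lay between -0.11 and 0.19. Against WT the KO median was 0.19, 0.29 and 0.22 in EB and 0.15, 0.35 and 0.38 in NPC, and that of mCaPS was -0.24, -0.21, -0.32, -0.34, -0.17 and -0.14 in the same order. The other autosomes lay between -0.23 and 0.12 for KO minus WT and between -0.21 and 0.16 for mCaPS minus WT. On day 0 chromosome 6 in KO minus WT was at -0.18 in EB and -0.23 in NPC, about as far from 0 as chromosome 8 or farther. These medians carry no test.

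**Figure D5:**
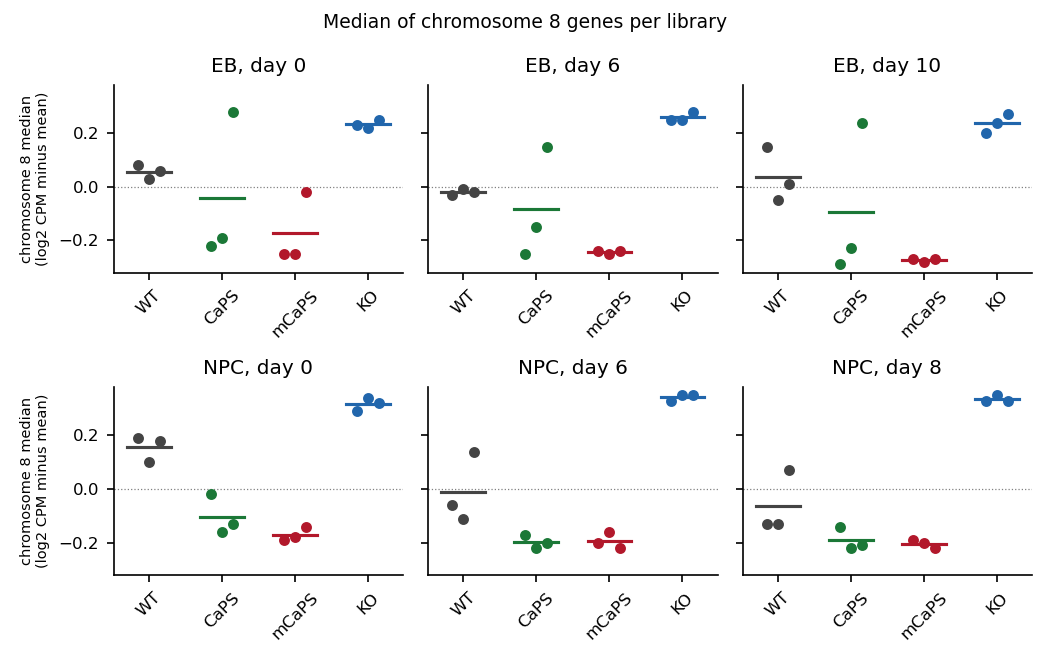
Median of chromosome 8 genes (log2 CPM minus the mean over libraries, relative to autosomes; y axis) in the WT, CaPS, mCaPS and KO libraries of both series by day; points are libraries, lines are means of 3 and the dotted line is 0. KO minus mCaPS comes to 0.44 to 0.54.

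The mCaPS and KO lines were set against each other on the last day because both differed from WT; this comparison was chosen after the data had been examined. In embryoid bodies naive pluripotency genes were lower and cardiac genes higher in mCaPS. Gdf3 was at -4.53 ± 0.64, Dppa5a, a stem cell gene, at -4.62, Tdh, a threonine-degrading enzyme of stem cells, at -5.03 and Pou5f1 at -2.21, while Myl7 (3.98), Myh6 (3.79) and Grb10 (5.27 ± 0.36) were higher. Paired by number within the day, Dppa5a and Tdh had an adjusted p of 0.0823 and 0.0623. The naive list was lower in 13 genes, or 18 adjusted over the list alone (adjusted p = 4.87e-25, and adjusted p = 0.0264 with an estimated correlation). The mesoderm list was higher in 4, or 11 (adjusted p = 2.71e-10, estimated adjusted p = 0.317). Cbx7 was lower by -2.39 ± 0.55 (adjusted p = 0.0205, and 0.221 without KO replicate 3), and Cbx2 was at 0.21. Paired by number within the day, the estimated adjusted p was 0.186 for the naive list and 0.036 for the mesoderm list. The naive mean was 2.99 to 3.09 in mCaPS and 3.32, 5.08 and 5.73 in KO replicates 1, 2 and 3.

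On NPC day 8 neuron genes were lower in mCaPS than in KO, such as Gap43, a growth cone protein (-3.10 ± 0.53), Tubb2b (-2.15 ± 0.41) and Glra1 (-5.18), and Gata4 (4.09), Apoa1 (6.10) and Grb10 (5.56 ± 0.36) were higher. Of the neuron list 16 genes were lower, or 18 adjusted over the list alone (adjusted p = 2.11e-17, and adjusted p = 0.126 with an estimated correlation). Of the mesoderm list 10 were higher, or 13 (adjusted p = 8.07e-08, estimated adjusted p = 0.263). Paired by number within the day, the estimated adjusted p of the neuron list was 0.0028. KO replicate 3 lay at a neuron mean of 3.86, and the other KO libraries at 5.74 and 5.79. Cbx7 was at -1.09 ± 0.32 (adjusted p = 0.0393, 13 ± 2.14 against 27.6 ± 17.4 CPM), and Cbx2 at 0.23. By edgeR 38 genes were higher and 250 lower in mCaPS on EB day 10, and 440 and 704 on NPC day 8. Paired by number within the day, in a fit of the 2 lines only, 310 were higher and 416 lower in EB, and 2276 and 2100 in NPC. Most of the imbalance in EB was thus gone, but not through pairing alone. The 2 groups fitted alone without pairing gave 442 higher and 474 lower. With replicate number as a block in the fit of all 4 lines, 62 were higher and 339 lower. Of the 288 unpaired calls in EB, 211 were among the paired ones. In EB the total was 95, 58 or 43 without mCaPS replicate 1, 2 or 3 and 571, 140 or 33 without KO replicate 1, 2 or 3. In NPC it was 583 or 308 without mCaPS replicate 1 or 3 and 168, 301 or 2413 without KO replicate 1, 2 or 3.

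The change from day 0 to the last day was then set against that of WT. For CaPS no gene passed by edgeR in either series (0 in EB with 314 at an unadjusted p below 0.05 and 0 by DESeq2; 0 in NPC with 643 and 1 by DESeq2). Without CaPS day 10 replicate 1 or 2 the EB count was 1, and without CaPS day 8 replicate 1 the NPC count was 2. Cbx2 was at -0.12 ± 0.54 in EB and -0.60 ± 0.34 in NPC. Neuron genes were higher as a list in EB (adjusted p = 4.77e-12, and adjusted p = 0.0813 with an estimated correlation; 6 adjusted over the list alone) and lower in NPC (adjusted p = 1.22e-08, estimated adjusted p = 0.316).

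Naive pluripotency genes fell less in CaPS-R embryoid bodies than in those of WT. Zfp42, a marker of naive stem cells, went from 365 to 123 CPM in CaPS-R and from 435 to 13.8 in WT (a difference of 3.41 ± 0.85). Tcl1 (5.24 ± 0.91), Nr0b1 (4.32 ± 1.05), Prdm14 (3.58 ± 0.79), Gdf3 (3.52 ± 0.73) and Dppa4 (2.81 ± 0.57) moved the same way. The naive list was higher in 6 of its genes, or 19 adjusted over the list alone (adjusted p = 3.06e-24, and adjusted p = 0.0131 with an estimated correlation). Usp18 (-5.58 ± 0.75) and Irf7 (-4.54 ± 0.72), both known as interferon-induced genes, and the blood regulator Lmo2 (-3.69 ± 0.66) were lower. Cbx2 was at -0.71 ± 0.54 (adjusted p = 0.721), and Cbx7 in CaPS-R was not analysed here. Among NPC changes the collagens Col6a1 (4.76 ± 1.00), Col6a2 (4.13) and Col5a1 (3.87), Twist2 (6.95) and Hoxc4 (3.18) were higher and the meiotic gene Sycp3 (-3.55 ± 0.69) and the germ cell factor Dmrt1 (-4.24) lower. The fibroblast list was higher in 4 genes, or 16 over the list alone (adjusted p = 8.98e-15, estimated adjusted p = 0.0931), and the germline list lower in 1, or 6 (adjusted p = 4.41e-09, estimated adjusted p = 0.0931).

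By edgeR 77 genes were higher and 19 lower in the change of CaPS-R in EB, and 97 and 9 in NPC. CaPS-R counts came in separate tables, so any difference in how those tables were made is shared by all their libraries. In NPC the median of all genes lay at 0.139 with TMM and at -0.039 with DESeq2 size factors, which gave 61 higher and 10 lower genes. In EB the total was 38 or 39 without WT day 0 replicate 2 or 3, 23, 31 or 51 without WT day 10 replicate 1, 2 or 3, and 49 without CaPS-R day 10 replicate 1. In NPC it was 31, 51 or 253 without WT day 0 replicate 1, 2 or 3, 29, 70 or 42 without WT day 8 replicate 1, 2 or 3, 40, 205 or 59 without CaPS-R day 0 replicate 1, 2 or 3, and 62 without CaPS-R day 8 replicate 1.

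Lines were also compared with each other through their changes against WT. Of the genes changed in mCaPS and in KO in the same direction, 21 higher and 71 lower were shared on EB day 0 (chance 0.09 and 0.53). The counts were 21 and 70 on day 6 (0.03 and 0.37), and 25 and 74 on day 10 (0.07 and 0.61). In the NPC series 132 and 266 were shared on day 0 (4.49 and 10.93), 1 and 0 on day 6, and 2 and 0 on day 8. On NPC day 0 the shared WT libraries had a fibroblast and feeder mean of 4.56 to 6.95. It was 3.26 to 3.76 in mCaPS and 3.17 to 3.65 in KO, and its part in the overlap was not tested. Simulated unchanged groups with shared WT controls gave 0 shared genes in 5 simulations of each day. Each such group had at most 1 changed gene, so hardly any could be shared. The 0 therefore does not show how many of the real shared genes come from the shared controls. These simulations drew mCaPS and KO libraries independently, although those with the same number were alike (median r = 0.33 in EB and 0.55 in NPC), which may raise such overlaps. The covariance of the changes of CaPS and mCaPS across genes was 0.055 on EB day 10 and 0.852 on NPC day 8, where shared controls alone gave 0.225 and 0.213, and that of CaPS and KO was 0.233 and 0.327, against 0.228 and 0.209. With 3 WT libraries the controls cannot be split between lines, so part of any excess may come from them. The simulations drew WT and CaPS libraries independently, although those with the same number were alike (median r = 0.77 in EB and 0.64 in NPC). Such pairs lower the covariance that shared controls give, so the simulated values are not exact references for CaPS.

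Day 0 was measured in both series. Of 162 genes changed in mCaPS on EB day 0 and tested in NPC, 106 (65.4%) had the same sign there, and 3 higher and 2 lower were changed in both (chance 0.5 and 2.3). For KO 72 of 114 (63.2%) had the same sign, and 0 higher and 2 lower were changed in both (chance 0.8 and 2.6); for CaPS 0 genes were changed in EB. Looked up from NPC to EB, 70.3% of 536 genes of mCaPS and 71% of 978 of KO had the same sign. Across 17345 genes, which are not independent replicates, the correlation between series was 0.12 for CaPS, 0.15 for mCaPS and 0.16 for KO.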

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

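All tests in this part, other than those of the change of CaPS-R against WT, were chosen only after the result was seen. The change of CaPS-R from day 0 to the last day differed from that of WT in 96 genes in EB and 106 in NPC by a test of the difference itself. Between mCaPS and KO, 288 genes differed on EB day 10 and 1144 on NPC day 8.

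Genes of chromosome 8 were higher in KO than in mCaPS by a median of 0.44 to 0.54 in every day and series, part of the genes that differ between these lines. In 5 equal stretches of the chromosome the median lay between 0.35 and 0.63 over all days, and 3 copies against 2 would give 0.585, so an extra copy of chromosome 8 in the KO cells, perhaps in a part of them, may account for it. A bias by gene length is argued against, since the median on NPC day 8 was 0.56 after matching genes by exon length. WT lay between the 2 lines, with KO minus WT at 0.15 to 0.38. CaPS minus WT was at -0.28, -0.16 and -0.11 on NPC days 0, 6 and 8, near mCaPS minus WT (-0.34, -0.17 and -0.14). In EB CaPS minus WT was at -0.1, -0.07 and -0.14, with CaPS replicate 3 apart from the others. Medians of single WT libraries in NPC ranged from -0.13 to 0.19. Which line departs from 2 copies was thus not settled. Off chromosomes 8 and Y, 38 genes were still higher and 212 lower in mCaPS in EB and 430 and 506 in NPC, and an effect of the CBX7 form on this chromosome was not tested apart from copy number.

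Most genes that differed from WT in mCaPS in embryoid bodies also differed in KO, 25 higher and 74 lower on day 10. Of the 74, 42 have a named pseudogene copy (56.8%, against 1.6% of all genes tested; Fisher's exact test, two-sided p = 9.99e-57) and 34 are ribosomal protein genes, so reads shared between genes and their copies may account for these. Of 98 genes changed the same way in both lines and tested in NPC, 94 (95.9%) had a day 0 level in WT of the NPC series nearer to EB mCaPS and KO than to EB WT. For the 92 genes shared on EB day 0 this held for all 92, with a median distance of 0.18 to mCaPS and KO and 2.84 to WT, and NPC CaPS gave 92 as well. A difference between library sets, with the EB libraries of WT and CaPS standing apart, may thus account for most of this pattern. An effect of the CBX7 form as its whole cause is argued against by those levels, and an effect in embryoid bodies alone by its presence on day 0. The sets also lay apart in Gapdh (18.6 to 41.2 CPM outside Rn45s in mCaPS and KO, and 5.1 to 13.2 or 79.7 to 623 in WT and CaPS). A further effect of the forms in EB stays open, because line and library set run together there.

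On NPC day 8 neuron genes were lower and fibroblast genes higher in mCaPS than in WT, as lists that did not pass with an estimated correlation (estimated adjusted p = 0.0963 and 0.332). Feeder cells carried over from day 0 are argued against, since the fibroblast list had a median of -3.4 on day 0 and 2.37 on day 8. A difference between library sets is argued against as the whole cause, since the median of the neuron list was -3.72 in mCaPS and -0.78 in KO. A shift of mCaPS cells from neural to mesodermal fates is a candidate explanation, and so is a trait of the clone or culture of each line, which the design does not part from the CBX7 form. CaPS replicates 2 and 3 and KO replicate 3 also had low neuron means on that day (3.53, 4.79 and 3.86), so libraries varied in this direction within other lines.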

How the results depend on the processing

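Tests chosen only after the result was seen were those without Rn45s, without the 2 EB libraries highest in Rn45s, without the 6 EB libraries of WT and CaPS numbered 1, with replicate blocks within each day, and without genes that have or are named pseudogene copies, and every test of mCaPS against KO. Counts of changed genes moved widely with the method and with single libraries, and where no cause is given the cause was not tested. A count within 1.5 times the reported one is taken as unmoved, and counts are given in the order of days. Leaving out Rn45s moved 0 of 28 counts. DESeq2 size factors left 31 of 32 unmoved, and CaPS against WT on EB day 10 gave 7.

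Without the low-count filter 27 of 32 were unmoved, and fewer genes passed among more genes tested for CaPS against mCaPS on NPC day 8 (144), mCaPS against WT on NPC day 6 (256) and the change of CaPS-R (61 in EB, 65 in NPC), while CaPS against WT on NPC day 6 gave 1. Replicate number as a block gave 1 and 1 for CaPS against WT on NPC days 0 and 6, 246 for mCaPS against WT on EB day 0, 542 for CaPS against mCaPS on NPC day 8 and 157 for the change of CaPS-R in EB. It changed no other count by more than 1.5 times. Blocks within each day, for lines whose libraries pair by number, gave 0 for CaPS against WT on EB day 10, 55, 28 and 251 on NPC days 0, 6 and 8, and 726 in EB and 4376 in NPC for mCaPS against KO.

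Fitting the 2 compared groups alone, with fewer libraries to estimate the spread, left 10 of 28 unmoved. It gave 0 for CaPS against WT on EB day 10 and on NPC day 8, 42 for mCaPS against WT on EB day 0 and 1267 and 2020 on NPC days 6 and 8, and 73 for KO against WT on EB day 10 and 312, 10 and 3 in NPC. CaPS against mCaPS gave 31, 58 and 103 in EB and 17, 1 and 0 in NPC, mCaPS against KO 916 in EB and 119 in NPC, and WT EB day 10 against day 0 gave 3145.

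DESeq2 gave more genes in 26 of 32 results. These were 75 and 74 for CaPS against WT on EB days 6 and 10 and 8, 119 and 226 in NPC, 400, 146 and 217 for mCaPS against WT in EB and 1067 and 1118 on NPC days 0 and 6, and 181, 185 and 364 for KO against WT in EB and 1594, 8 and 130 in NPC. CaPS against mCaPS gave 325, 518 and 942 in EB and 682 and 968 on NPC days 0 and 8, and mCaPS against KO 627 in EB and 1857 in NPC. The change of CaPS gave 1 in NPC, and that of CaPS-R 315 in EB and 265 in NPC.

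Without the 2 EB libraries highest in Rn45s the counts were 1 and 2 for CaPS against WT on days 6 and 10, 121 for CaPS against mCaPS on day 6, 280 for KO against WT on day 10 and 549 for mCaPS against KO. Without the 6 EB libraries numbered 1 they were 180 and 199 for mCaPS against WT on days 6 and 10, 220, 193 and 249 for KO against WT, 244 and 817 for CaPS against mCaPS on days 0 and 6, and 612 for mCaPS against KO. Without genes that have or are pseudogene copies they were 107, 44 and 69 for mCaPS against WT in EB, 64, 57 and 92 for KO against WT and 85 for CaPS against mCaPS on day 0, and 21 of 28 counts were unmoved.

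Leaving out 1 library at a time gave these lowest and highest counts. In EB they were 0 and 24 for CaPS against WT on day 6, 0 and 83 on day 10, 97 and 287 for mCaPS against WT on day 0, 75 and 120 for KO against WT on day 6, and 85 and 298 on day 10. For CaPS against mCaPS they were 86 and 366 on day 6 and 173 and 738 on day 10, and for mCaPS against KO 33 and 571. The change gave 0 and 1 for CaPS and 23 and 76 for CaPS-R. In NPC they were 0 and 7, 0 and 201, and 1 and 801 for CaPS against WT, 91 and 717, 0 and 735, and 1205 and 3150 for mCaPS against WT, and 225 and 1984 on day 0 and 5 and 122 on day 8 for KO against WT. For CaPS against mCaPS they were 61 and 821, 0 and 1, and 1 and 805, and for mCaPS against KO 168 and 2413. The change gave 0 and 2 for CaPS and 29 and 253 for CaPS-R. Counts for WT over time (3997 to 4686 in EB, 8076 to 8589 in NPC) moved less.

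At an adjusted p below 0.01 the genes changed in both series on day 0 came to 0 for mCaPS and 1 for KO. Of the list tests, 10 passed with an estimated correlation. With genes of at least 10 CPM the covariance of CaPS and mCaPS turned from 0.055 to -0.016 on EB day 10, and was 0.34 on NPC day 8, and that of CaPS and KO was 0.054 and 0.086. Simulated unchanged groups gave 0.078 and 0.054 for CaPS and mCaPS over these genes, and 0.079 and 0.055 for CaPS and KO. Leaving out 1 WT library, which leaves fewer shared controls, gave 0.191 to 0.271 and 0.862 to 1.208 for CaPS and mCaPS, and 0.354 to 0.519 and 0.4 to 0.616 for CaPS and KO. Among single genes named as changed, 199 of 199 passed with DESeq2, with size factors and with a replicate block, 190 of 199 without the low-count filter and 137 of 183 in fits of the 2 groups alone, and no named gene turned its direction. Leaving out 1 library ended 239 of 1290 such calls.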

Other observations

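Lists of imprinted and of Y-linked genes were chosen only after the result was seen, and so were the splits of mCaPS against KO, those by pairs and the fit used for the splits. The other splits were planned. Imprinted genes, which are expressed from the copy of 1 parent, were changed mostly in mCaPS of the NPC series, and their number was not tested. In each EB comparison of a line with WT at most 1 was higher and 1 lower. For CaPS against WT in NPC 0 were higher and at most 2 lower. On NPC day 8, 17 of 33 measured imprinted genes were higher in mCaPS than in WT and 4 lower, and on NPC day 6, 11 were higher and 1 lower. The day 6 calls depended on single libraries, since 0 genes of any kind were higher without WT replicate 2 or mCaPS replicate 3. Leaving out a library also lowers the power of the test, so this does not show that the day 6 differences are absent. With all libraries, DESeq2 gave 602 higher and 516 lower genes of any kind that day. On day 8 mesoderm means rose in the same libraries (3.23 to 3.88 against 1.13 to 1.91 in WT), so a change of cell types was not parted from one of imprinted genes. Higher on day 8 were the growth genes H19 (3.62 ± 0.69), Igf2 (3.39 ± 0.79) and Dlk1 (3.54 ± 0.69) and the transcription factor Peg3 (2.36 ± 0.45). Lower were Kcnq1ot1 (-2.50 ± 0.36), Peg13 (-3.05 ± 0.56), Nnat (-1.86 ± 0.37) and Peg12 (-2.35 ± 0.46). Kcnq1ot1 was lower in mCaPS than in WT also on NPC day 0 (-2.50 ± 0.36) and day 6 (-2.40 ± 0.36, with an adjusted p of 0.0817 without mCaPS replicate 3). In EB, where line and library set run together, it was at -1.56 ± 0.47, -2.50 ± 0.48 and -1.45 ± 0.46 on days 0, 6 and 10 (adjusted p = 0.128, 0.00349 and 0.267). In WT itself 17 of the 33 rose and 3 fell by NPC day 8, and 17 rose and 1 fell by EB day 10. In KO against WT on NPC day 0, 4 were higher and 3 lower, and on NPC day 8, 2 and 1.

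Y-linked genes, of which 4 were measured, summed to 6 to 15.2 CPM in the KO libraries of NPC and to 6.7 to 14.9 CPM in KO replicates 2 and 3 of EB, while KO replicate 1 of EB had 60.4 to 88.9 CPM. CaPS day 0 replicate 3 (11.2 CPM) and mCaPS day 0 replicate 3 (14.5 CPM) of EB were also low, and the other libraries had 46.3 to 404 CPM. Chromosome 8 genes were high in CaPS replicate 3 of EB, with medians of 0.28, 0.15 and 0.24 on days 0, 6 and 10 against -0.29 to -0.15 in the other CaPS libraries of that series. Replicate 3 thus stood apart in chromosome 8 on all 3 days of EB, and in lineage genes on days 6 and 10.

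Each pair of groups was also compared over the 10 ways to split its 6 libraries, which are too few for a share under 0.05. For mCaPS against WT the real split gave 163, 96 and 126 genes in EB and the highest other split 2, 0 and 0, and in NPC 538, 395 and 3288 against 1, 0 and 0. For KO against WT these were 114, 115 and 156 against 0, 0 and 59 in EB, and 983, 5 and 9 against 2, 0 and 0 in NPC. For WT over time they were 5195 against 2 in EB and 9342 against 0 in NPC. For CaPS against mCaPS they were 141, 199 and 565 against 555, 0 and 0 in EB, and 375, 2 and 284 against 1, 0 and 85 in NPC. The count of splits as large, the real one included, was 1 in these comparisons except CaPS against mCaPS on EB day 0, where it was 2. There the split with 555 genes set CaPS replicates 1 and 3 with mCaPS replicate 3 against the rest, which points to a structure of the samples.

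For CaPS against WT the real split gave 0, 0 and 1 genes in EB and the highest other split 25, 0 and 0, and in NPC 0, 0 and 2 against 824, 85 and 613. Splits as large numbered 10, 10 and 1 in EB and 10, 10 and 4 in NPC. Counts many times the real one point to a structure of the samples, and on NPC day 8 the split with 613 genes set CaPS replicate 1 with WT replicates 1 and 2 against CaPS replicates 2 and 3 with WT replicate 3. Among the 4 splits that part all 3 pairs of WT and CaPS libraries with the same number, the highest other count was 0 on every day of both series, and the splits with more genes put at least 1 pair on the same side. For mCaPS against KO the real split gave 288 genes in EB with 91 as the highest other, and 1144 in NPC with 1677, so 1 and 2 splits were as large. Among the 4 splits that part all 3 pairs the highest others were 81 and 0.

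For the change over time 60 of the 200 possible splits of 12 libraries were drawn. The change of CaPS-R gave 96 genes in EB and 106 in NPC, and 10 and 8 of the 60 splits gave as many, up to 1625 and 2660 genes. CaPS-R and WT come from separate tables, and splits that swap different numbers of libraries on the 2 days carry the difference of the tables into the change. Among the 28 other splits with the same number swapped on both days the highest counts were 1 and 3, but these hold that difference within groups, so the splits do not show whether chance made the counts. The change of CaPS gave 0 genes in both series, and 60 of 60 splits gave as many, up to 2428 in EB and 201 in NPC. Splits with several times the real count point to a structure of the samples.

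The splits were first made in fits of the compared libraries alone, and were moved to the fits with all lines after those counts had been seen, so that they test the printed results. With the compared libraries alone, the change of CaPS-R gave 68 genes in EB and 25 in NPC, and 4 and 6 of 100 drawn splits gave as many, up to 2490 and 4195. These splits mix the tables in the same way and decide nothing either. In those fits CaPS against WT gave 0 genes in all 10 splits on every day of both series. CaPS against mCaPS gave 31 genes on EB day 0 with 0 as the highest other, and 0 genes on NPC day 8 in all 10 splits. For mCaPS against KO the real split gave 916 genes in EB and 119 in NPC, with 0 as the highest other in both. The large counts of other splits in CaPS against WT, CaPS against mCaPS on EB day 0 and mCaPS against KO were therefore seen only in the fits with all lines.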
